A study of Homo sapiens with 4 samples.

How the data were processed

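DNA methylation was measured by bisulfite sequencing after capture with SeqCap Epi probes in 4 libraries of MCF7 cells, an established oestrogen receptor-positive breast cancer line. Of these, 2 libraries came from cells kept at 21% oxygen (normoxia) and 2 from cells kept at 0.5% oxygen (hypoxia), each for 24 h. Bisulfite turns unmethylated cytosine into uracil and leaves 5-methylcytosine and 5-hydroxymethylcytosine unconverted, so both modified bases are read as methylated. Per the labels, the extraction buffers of all libraries held deferoxamine, an iron chelator. Each library was assigned to its group and experiment from its labels.

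The deposited count table holds raw, unnormalised counts per captured region, per the file headers: all counts and methylated counts in each library, for 240130 regions with a median length of 286 bp. The submitters' processing notes name Bismark 0.13.1 and the build hg19; the counting steps are not given in the sources used here. The header speaks of reads, but whether 1 count is a read or a CpG call is not given, so an interval computed from counts covers counting error only and may be too narrow. Coordinates are printed as the table gives them; whether the start is counted from 0 or 1 is not given. The authors' deposited table of results holds, for 80132 of these regions, a difference in methylation fraction and a p-value per region; the test behind that p-value is not given. The difference equalled the mean of the hypoxic fractions minus the mean of the normoxic fractions, to within 4.91e-08. The regions in it were those with more than 20 counts in every library and more than 400 counts in all, which 80136 regions met, less 4 whose level was constant.

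Library totals were 38359825 and 22332539 counts in normoxia 1 and 2, and 46542428 and 27659193 in hypoxia 1 and 2. The median count per region was 66 and 39 in the normoxic libraries and 75 and 47 in the hypoxic libraries. The 95% Wilson interval of a library's methylated share reached between 0.0139 and 0.0201 percentage points to either side.

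Regions were tested with at least 10 counts in every library and at least 1 methylated and 1 unmethylated count over the 4 libraries, which left 188311 regions (78.4%). Methylated and unmethylated counts entered the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with 1 coefficient per library, 1 for methylated counts and 1 for hypoxia, no dispersion trend and robust estimation. Benjamini-Hochberg adjusted p-values under 0.05 were taken as past the threshold. A level is the methylated percentage of counts in a region; differences are hypoxia minus normoxia, in percentage points. The level over all regions was compared by a two-sided exact permutation test, which with 2 libraries against 2 cannot give p below 0.333. Regions were also divided by their mean level over the 4 libraries at 20% and 80%, and by whether the table gave a gene ID. Mean levels per gene ID (at least 3 tested regions) and per 1 Mb bin (at least 20 tested regions) were tested with limma 3.58.1; these analyses were added after the data had been examined, as was the choice of the gene families below.

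The series' design text places 1 normoxic and 1 hypoxic culture in each of 2 independent experiments, so the experiment number pairs the libraries. Across regions, the differences of normoxia 2 from normoxia 1 and of hypoxia 2 from hypoxia 1 had a Pearson correlation of 0.0515. The fit without the experiment was chosen before the data were examined, with the fit holding experiment as a block as an alternative.

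Genes were named only where the deposited tables describe a product beside the ID. This gave 24 genes over 411 regions, in 3 families (18 GALNT, 4 PFKFB and 2 PREX genes), whose symbols and chromosomes were checked against the RefSeq gene table of assembly GRCh38.p14. That table, as used here, holds an Ensembl ID for 0 of its 59792 genes, so the 22447 gene IDs of the deposited tables could not be looked up in it, and its coordinates were not used because its build differs. The 12 gene lists fixed before the data were examined (377 genes) were therefore not tested; of their genes, 2 (PFKFB3 and PFKFB4) were named in the tables. The genes that the naming rule lists one by one (TET1, TET2, TET3, DNMT1, DNMT3A, DNMT3B, CA9, VEGFA and EGLN3) were not analysed here by name, for the same reason. Promoter, exon and intron positions were not used here. Families were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry. The regions named in the text were, by a rule fixed beforehand, the 10 with the greatest gain and the 10 with the greatest loss past the threshold, with a mean of at least 30 counts and the same direction in both experiments, or every such region if fewer.

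The edgeR fits, the quasi-binomial model and limma were tried on data simulated with no difference between experiments. With 200 of 186997 simulated regions changed, the edgeR fit gave 56 calls, of which 3 were false, and recovered 3% of 4-fold and 50% of 16-fold changes in odds. The fit with experiment as a block gave 113 calls, of which 33 were false, and recovered 10% and 70%. The quasi-binomial model gave 120 calls, of which 6 were false, and recovered 40% and 74%. With means of 13329 genes simulated and 200 changed, limma recovered 92.5% of shifts of 10 points, with 13 false calls among 198. Such shifts exceed the median difference of 1.18 points over real genes, so this recovery does not bear on changes of that size. With 2311 bins and 200 changed it recovered 70.5% of shifts of 3 points, with 3 false calls among 144. With experiment as a block, limma made 15 false calls among 204 for genes. For bins, the block fit recovered 53.5%, with 0 false calls among 107. The noise of these simulated means was independent and depended on the number of regions alone. Alternatives were DESeq2 1.42.0, a quasi-binomial model, the edgeR likelihood ratio test, Fisher's exact test on summed counts, TMM scaling, centred log ratios, an effect of at least 5 points, coverage minimums of 30 and 1, autosomes, regions of the authors' table, the block, and leaving out each library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used for summaries.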

Results

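DNA methylation was measured over 240130 captured regions in MCF7 cells, an oestrogen receptor-positive breast cancer line, grown for 24 h at 21% oxygen (normoxia, n = 2) or 0.5% oxygen (hypoxia, n = 2). Each of 2 independent experiments supplied 1 library of each group. The libraries held 38359825 counts (normoxia 1), 22332539 (normoxia 2), 46542428 (hypoxia 1) and 27659193 (hypoxia 2). Coordinates are those of hg19.

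The series asks whether low oxygen raises DNA methylation, which its title ties to lower activity of the TET enzymes, the dioxygenases that oxidise 5-methylcytosine. Over the 188311 tested regions, 62.8% ± 0.258 of counts were methylated in hypoxia (SD, n = 2) and 61.6% ± 0.700 in normoxia (SD, n = 2), a difference of 1.198 points, which was 0.703 points without normoxia 1. Within experiment 1 the methylated share was higher in hypoxia by 1.87 points and within experiment 2 by 0.520 points, with an SD of 0.958 between experiments. When each region had equal weight, the mean level was 64.6% ± 0.450 in hypoxia and 63.4% ± 0.0165 in normoxia (SD, n = 2 each), and the differences were 0.930 points in experiment 1 and 1.59 points in experiment 2. Both hypoxic libraries lay above both normoxic libraries on each measure. The exact permutation test gave p = 0.333, the smallest value that 2 libraries against 2 allow, so the difference did not reach the threshold. Experiment 1 had the greater difference in the share of counts and experiment 2 in the mean level. The share of counts also depends on where counts fall. Regions over 80% methylation held 49.4% of counts in normoxia 1 and 51.2% in hypoxia 1, against 50.2% in normoxia 2 and 50.4% in hypoxia 2. Regions under 20% held 23.9% and 23.1%, against 22.7% and 23.9%. The difference in the share of counts therefore mixes coverage with methylation level, which equal weight per region avoids.

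The size of the difference varied with the methylation level of the region, and the order of the classes depended on the scale. In the 59773 regions of 20 to 80% methylation the mean difference was 1.72 points ± 0.505 (SD, n = 2 experiments), and in the 92578 regions over 80% it was 1.36 points ± 0.665. In the 35960 regions under 20% it was 0.244 points ± 0.111. The mean level of these last regions was 6.42% and 6.36% in hypoxia 1 and 2, against 6.10% and 6.20% in normoxia 1 and 2. Regions of 70 to 80% methylation showed mean differences of 1.48 points in experiment 1 and 2.66 points in experiment 2, where normoxia 2 differed from normoxia 1 by -0.236 points and hypoxia 2 from hypoxia 1 by 0.948 points. At 50 to 60% methylation hypoxia 2 differed from hypoxia 1 by 1.25 points, close to the difference of 1.33 points between the groups in experiment 1. The median difference was 1.68 points at 20 to 80%, 1.14 points over 80% and 0.155 points under 20%; without hypoxia 1 the last was -0.0115 points. On the log2 odds scale of the edgeR test the median was greatest over 80%, at 0.22, against 0.11 at 20 to 80% and 0.06 under 20%.

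**Figure D1:**
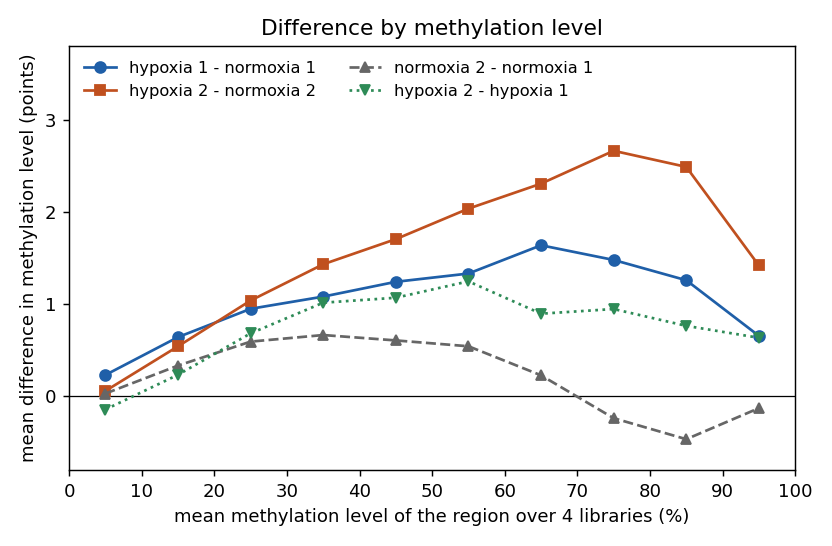
Mean difference in methylation level (points, y axis) in classes of regions by their mean level over the 4 libraries (percent, x axis, 10 points wide); circles and squares are hypoxia minus normoxia within experiments 1 and 2, and triangles are the differences between replicates, normoxia 2 minus normoxia 1 (pointing up) and hypoxia 2 minus hypoxia 1 (pointing down). Both hypoxic lines lie above 0 in every class and reach 1.64 points (experiment 1) and 2.66 points (experiment 2), while the replicates differ by -0.464 to 0.666 points in normoxia and by -0.142 to 1.25 points in hypoxia.

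The difference was spread over the genome. Each of the 22 autosomes and the X chromosome had a higher mean level in hypoxia in both experiments, with mean differences between 0.939 points on the X chromosome and 1.48 points on chromosome 15. Of 2311 bins of 1 Mb, 92.0% had a higher mean level in hypoxia, and 1761 (76.2%) did so in both experiments, where 75.4% would be reached if the experiments were independent of each other. Regions with a gene ID differed by 1.23 points ± 0.466 and regions without one by 1.32 points ± 0.468 (SD, n = 2 experiments). Of the regions past the edgeR threshold described next, 2 had a gene ID (of 127602 tested) and 2 had none (of 60709), with adjusted p = 0.898 by Fisher's exact test (two-sided, 3 tests), which so few regions leave with little power. At an unadjusted p under 0.05 in edgeR there were 6574 regions with a gene ID and 2690 without, an odds ratio of 1.17 (Fisher's exact test, adjusted p = 2.97e-11); regions are not independent replicates, so that p is too small. With limma, 0 bins passed the adjusted threshold, while 579 were higher and 1 was lower at an unadjusted p under 0.05; these were 151 and 1 without hypoxia 2, 318 and 0 without normoxia 2, and 472 and 9 without normoxia 1. With experiment as a block, 242 bins passed as higher and 1 as lower; without normoxia 1, 16 passed as higher and 0 as lower. On simulated bins the fit with the block made 0 false calls among 107. Those bins held independent noise set by the number of regions alone, with no difference between experiments and no shift shared by all bins. They therefore cannot check the bins that passed with the block. In the block fit, bins on different chromosomes shared 1 standard error, such as 0.748 for bins on chromosomes 4 and 10. Its p-values thus rest on a spread pooled over bins and not on each bin's own spread between experiments. The fit also set each bin against no change, while the median difference over bins was 1.26 points. The bins that passed are therefore not changes shown 1 by 1 to repeat between experiments. In limma without the block, a split of the libraries by experiment gave 36 bins past the threshold, against 0 for the split by oxygen.

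**Figure D2:**
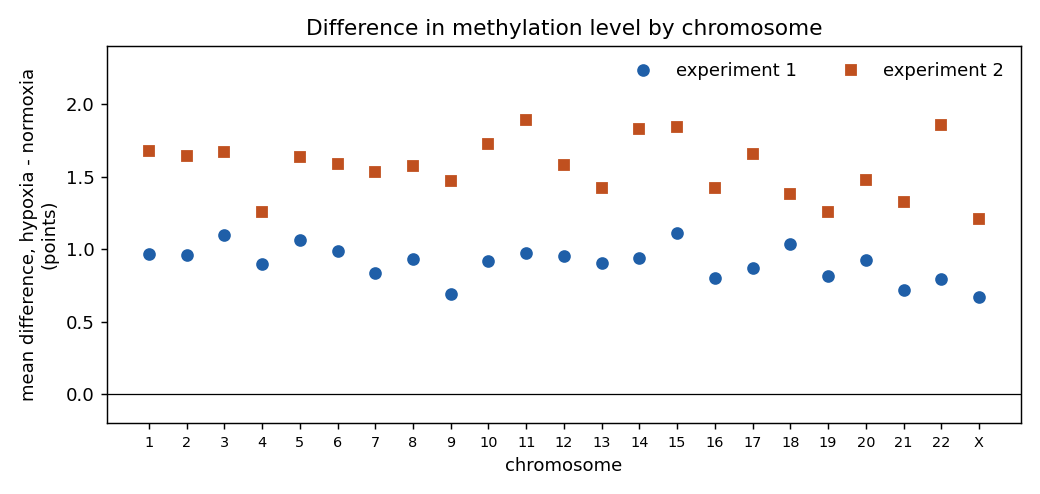
Mean difference in methylation level, hypoxia minus normoxia (points, y axis), over the tested regions of each chromosome (x axis), in experiment 1 (circles) and experiment 2 (squares). All 23 chromosomes lie above 0 in both experiments.

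Single regions past the threshold were few: 1 region rose and 3 fell in hypoxia (edgeR quasi-likelihood test, adjusted p under 0.05). On simulated counts this test recovered 3% of 4-fold and 50% of 16-fold changes in odds, so many changes could be missed. The region that rose lies at chromosome 19, 11517008 to 11517564, and carries the gene ID ENSG00000205517. Its level was 50.7% ± 1.55 in hypoxia and 18.6% ± 2.88 in normoxia (SD, n = 2 each, 199 to 456 counts per library; edgeR adjusted p = 0.00544). The region at chromosome 10, 18429583 to 18429850, with the gene ID ENSG00000165995, fell from 64.8% ± 10.9 to 16.8% ± 5.09 (80 to 235 counts; edgeR adjusted p = 0.00355). The files do not pair either ID with a gene name. A region without a gene ID at chromosome 1, 29450476 to 29450950, fell from 50.6% ± 0.862 to 6.67% ± 5.72 (41 to 140 counts; edgeR adjusted p = 0.0112). A second one, at chromosome 16, 85269349 to 85269584, fell from 95.04% ± 3.79 to 67.1% ± 8.16 (144 to 269 counts; edgeR adjusted p = 0.00355). Each of these 4 regions changed in the same direction in both experiments. None of their tested neighbours within 5 kb (1 to 5 per region) shared the direction of its region in both experiments.

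**Figure D3:**
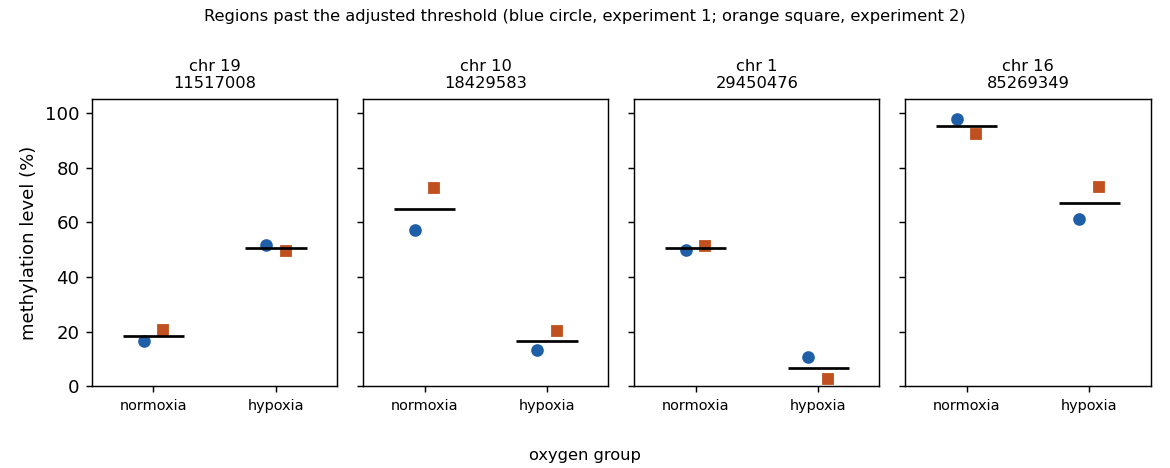
Methylation level (percent, y axis) in normoxia and hypoxia (x axis) of the 4 regions past the adjusted threshold, each titled by chromosome and start; circles are experiment 1, squares experiment 2 and bars group means. The region on chromosome 19 was higher in both hypoxic libraries and the other 3 were lower in both.

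At an unadjusted p under 0.05, 6879 regions were higher and 2385 lower, against 4708 expected in each direction by chance. Together these were 4.92% of the tested regions, no more than chance gives at that threshold. They were thus unequal in direction without being in excess in number. Of all tested regions, 61.0% had a higher fitted level in hypoxia. The median log2 odds ratio was 0.15. With log ratios centred, which takes that shift out, the median was -0.02 and the split at p under 0.05 was 3794 higher against 4251 lower, so that 47.2% were higher in place of 74.3%; the 4 regions stayed past the threshold. With experiment as a block, 49 regions passed as higher and 34 as lower, including those 4, in a fit that made 33 false calls out of 113 on simulated data. Those data held no difference between experiments, whereas in the real libraries that fit called 159 regions higher and 58 lower in experiment 2. The simulated rate of false calls therefore need not hold for the regions that passed with the block. No region passed with a coverage minimum of 30 (0 of 129263, edgeR, 4853 higher and 1545 lower at an unadjusted p under 0.05) or with DESeq2 (0, 1931 higher and 687 lower). The 4 regions held at least 41 counts in every library, so that minimum did not remove them. For the region on chromosome 16 the log2 odds ratio was -3.40 at minimums of 1, 10 and 30. Its unadjusted p in edgeR was 6.03e-14, 2.53e-08 and 2.42e-06 in that order. Its call thus depended on which other regions entered the fit. Leaving out 1 library changed which regions passed: 20 higher and 29 lower without normoxia 1, of which 1 was among the 4; 9 and 8 without normoxia 2, with all 4; 7 and 8 without hypoxia 1, with 2 of the 4; and 3 and 2 without hypoxia 2, with 2 of the 4. Leaving out normoxia 1 raised the adjusted p to 0.0635, 0.0905 and 0.0634 for the regions on chromosomes 1, 16 and 19. Leaving out hypoxia 1 raised it to 0.1 and 0.0671 for those on chromosomes 10 and 19, and leaving out hypoxia 2 to 0.13 and 0.0808 for those on chromosomes 1 and 19.

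Genes were compared by the mean level of their regions. Among 13329 gene IDs with at least 3 tested regions, 72.1% had a higher mean level in hypoxia, with a median difference of 1.18 points. None passed the adjusted threshold (0 with limma, and 0 with experiment as a block), while 859 were higher and 116 lower at an unadjusted p under 0.05 (361 and 89 without hypoxia 2, 1112 and 254 without normoxia 1). The deposited tables describe 24 genes by product, and none of these passed over all genes or adjusted over the list alone (0 and 0). The 18 GALNT genes encode the transferases that start mucin-type O-glycosylation and their relatives. They had a mean difference of 0.382 points, which was 0.238 points without hypoxia 1 and 0.251 points without normoxia 2, and 8 of them were higher and 2 lower in both experiments. GALNT9 (83 regions) was at 64.3% ± 0.578 in hypoxia and 62.9% ± 0.844 in normoxia, and GALNT6 (7 regions) at 50.4% ± 0.379 and 47.7% ± 0.575 (SD, n = 2 each). GALNT7 (12 regions) was at 63.4% ± 1.22 and 61.1% ± 1.1. GALNT11 (8 regions) was at 69.3% ± 1.17 in hypoxia and 73.6% ± 0.0478 in normoxia, with an unadjusted p of 0.0310 in limma.

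The 4 PFKFB genes encode the enzymes that set the level of fructose 2,6-bisphosphate, an activator of glycolysis. Their mean difference was 0.859 points, and 0.467 points without hypoxia 2. PFKFB3, over 31 regions, was at 68.4% ± 0.897 in hypoxia and 68.2% ± 0.164 in normoxia, and PFKFB4, over 5 regions, at 46.5% ± 0.753 and 44.7% ± 2.26 (SD, n = 2 each). PFKFB2 and PFKFB4 were higher in both experiments. The 2 PREX genes encode exchange factors for the GTPase Rac. Their mean difference was -0.571 points, with opposite signs in the experiments, and it ran from -2.02 points without hypoxia 2 and -1.97 points without normoxia 2 to 0.832 points without normoxia 1 and 0.883 points without hypoxia 1. Set against the median of 1.18 points over all genes, all 3 family means were lower. Camera, which compares a family with the other genes, placed all 3 below them and gave adjusted p = 0.543 for the GALNT genes, 0.767 for the PFKFB genes and 0.543 for the PREX genes, and adjusted p = 0.792 for each with an estimated correlation. Fry, which tests whether a family moves one way, gave adjusted p = 0.0467, 0.218 and 0.831 in that order. It sets a family against no change and not against the other genes, and 72.1% of all gene IDs were higher in hypoxia. Its value for the GALNT genes therefore does not set them apart from the other genes.

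**Figure D4:**
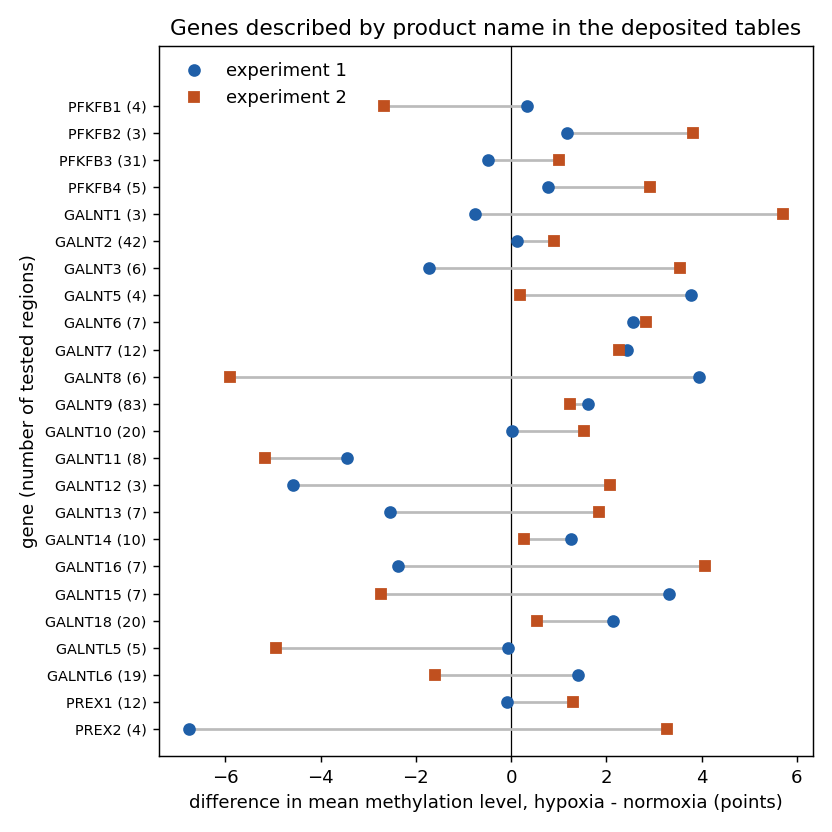
Difference in mean methylation level, hypoxia minus normoxia (points, x axis), of the 24 genes described by product in the deposited tables (y axis, number of tested regions in parentheses), in experiment 1 (circles) and experiment 2 (squares), joined by a line. Of the 24 genes, 10 lie above 0 and 2 below 0 in both experiments, and 12 have opposite signs.

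The differences found in experiment 1 were set against those in experiment 2, which share no library. Across the 188311 regions the Pearson correlation was 0.00423 and Spearman's was 0.0120; regions are not independent replicates, so no p is given. A higher level in both experiments was found in 32.5% of regions, against 32.2% if the experiments were independent, and a lower level in both in 17.3%. When hypoxia 1 was paired with normoxia 2 and hypoxia 2 with normoxia 1, the Pearson correlation was -0.0472. Across gene means the correlation was 0.0140, against -0.0673 with these crosswise pairs. Across 1 Mb bins it was 0.0524 (Spearman's 0.0439), against -0.468 (Spearman's -0.311) with the crosswise pairs. A difference between experiments enters the crosswise pairs with opposite signs and lowers their correlation, so the crosswise values are not those expected of no change.

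The authors' deposited table gives a difference and a p-value for 80132 of the regions. In the authors' deposited table, 63.2% of regions had a positive difference, with a median of 0.745 points, and 1556 regions were higher and 532 lower at p under 0.05. By chance 4007 regions would be expected below that threshold. After Benjamini-Hochberg adjustment of the p-values of the authors' deposited table, the lowest was 0.997, so 0 passed. Of the 4 regions past the threshold in the edgeR test, 3 are in the authors' deposited table, which gives them p-values of 0.0509 (chromosome 19), 0.0727 (chromosome 10) and 0.0596 (chromosome 16). At an unadjusted p under 0.05 in both, 482 higher regions were shared, against 68.6 expected of independent lists, and 113 lower regions, against 7.69; both lists rest on the same libraries.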

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

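The tests in this part, apart from the fit with experiment as a block, were chosen after the results were seen. The share of a library's counts that fell on a chromosome was not used in the comparisons. On 5 of 23 chromosomes both hypoxic libraries had a greater share than both normoxic libraries, by more than the gap between the normoxic libraries. The log2 ratio of hypoxia to normoxia was 0.0824 on chromosome 16, 0.0659 on chromosome 17, 0.0943 on chromosome 19, 0.0426 on chromosome 21 and 0.0992 on chromosome 22. The opposite order, beyond the same gap, was found on 2 chromosomes. Chance places both libraries of 1 group on top in 16.7% of cases, so that 3.83 of 23 chromosomes would be expected without regard to the gap, and shares of 1 library are not independent of each other.

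The mean gain over regions was weighed against technical explanations. Incomplete bisulfite conversion would add most where most cytosines are unmethylated, but regions under 20% gained 1.48 points less than regions of 20 to 80% (a difference of -1.48 points, greater than the spread between experiments), which argues against it. Depth was tested by setting the deeper against the shallower library of each group: the deeper one differed by 0.0233 points in normoxia and -0.636 points in hypoxia, and the value in normoxia missed the bound of 0 first set for excluding depth. A second bound was then set after seeing this value. A gain of the observed size per doubling of depth needs 3.35 points within normoxia and 3.22 points within hypoxia. The differences found were 0.00697 and -0.198 times these, which met the second bound. The deeper library of each group came from experiment 1, so a difference between experiments could hide an effect of depth, and depth is not excluded. In the share of counts, normoxia 2 differed from normoxia 1 by 0.990 points and hypoxia 2 from hypoxia 1 by -0.365 points. Better recovery of methylated molecules in the hypoxic libraries would raise the ratio of counts over 80% to counts under 20% in both experiments. That ratio moved by 0.1003 (log2) in experiment 1 and -0.0690 in experiment 2, a mean of 0.0156. The mean level rose more in experiment 2, where the ratio fell (1.59 points, against 0.930 in experiment 1). A ratio between regions cannot show unequal recovery within a region, so recovery cannot be told apart from the oxygen effect. The 3 splits of the 4 libraries are too few for a share under 0.05: the oxygen split put 61.0% of regions on the larger side, as 1 of 3 splits, and the highest other split 52.2%. An effect of oxygen on methylation stays open, as the difference between the groups that the design names.

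The small number of regions past the threshold, with a change not shared region by region between experiments, was weighed next. All 3 of the 3 splits gave at least the 4 regions of the oxygen split, and 3 splits are too few for a share under 0.05. Setting normoxia 2 and hypoxia 1 against normoxia 1 and hypoxia 2, which follows neither oxygen nor experiment, gave 11 regions. The highest count was 40, for the split by experiment. The 40 regions of that split point to a structure of the libraries by experiment, consistent with differences between experiments that exceed those between oxygen groups at single regions, and the fit with experiment as a block gave 49 higher and 34 lower. Counts that are not independent within a library also go with the data. In the sixth of regions with the fewest counts, libraries of 1 group differed by a chi-square of 1.504 per degree of freedom. Independent counts give 1, although variation between cultures may add to the value. In the sixth with the most counts it was 4.19 in normoxia and 4.53 in hypoxia. Over all sixths, libraries of 1 experiment differed by 2.09 and 2.05, and libraries of 1 oxygen group by 2.22 and 2.30. Low power can also leave few regions past the threshold. On counts simulated with no difference between experiments, the edgeR fit recovered 3% of 4-fold and 50% of 16-fold changes in odds. The quasi-binomial model recovered 40% and 74% of these, but in the real data it called 1 region higher and 0 lower. A test with more power on the simulated counts thus did not call more regions than edgeR. No test here separates these explanations.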

How the results depend on the processing

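The difference over all regions stayed positive, and within its spread between experiments, in all 11 alternatives. It ran from 0.520 (within experiment 2) to 2.14 points (median of region levels), and from 0.703 to 1.69 points when 1 library was left out. The values within experiments define that spread, so they could not fall outside it. Both hypoxic libraries lay above both normoxic libraries, so neither those values nor leaving out 1 library could change the sign. Of 47 alternative values of a difference over all regions, by level or by gene ID, 46 were positive. The exception was the median of regions under 20%, which ran from -0.0115 (without hypoxia 1) to 0.315 points without 1 library; the cause was not tested. The median of regions without a gene ID ran from 0.799 to 1.36 points without 1 library. Family means without 1 library, added after seeing the data, ran from 0.238 to 0.527 points for GALNT, 0.467 to 1.25 points for PFKFB and -2.02 to 0.883 points for PREX.

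Counts of regions depended most on the setting. Against 1 higher and 3 lower, the counts were 49 and 34 with experiment as a block, 0 and 0 with DESeq2, 1 and 0 with the quasi-binomial model, 51 and 34 with the likelihood ratio test, 2113 and 804 with Fisher's exact test on summed counts, which leaves out the spread between libraries, 1 and 5 with centred log ratios, 0 and 0 at a coverage minimum of 30, 39 and 30 at a minimum of 1, and 0 and 0 in regions of the authors' table, a setting added after seeing the data. Leaving out 1 library gave 3 to 20 higher and 2 to 29 lower; the lone library of a group is then assumed to vary like the other group. TMM, autosomes and the minimum effect gave 1 and 3. Called regions under 20%, at 20 to 80% and over 80% numbered 0, 3 and 1, against 16, 45 and 22 with the block, 0, 0 and 0 at a coverage minimum of 30 and 16, 33 and 20 at a minimum of 1, and ran over 1 to 13, 3 to 27 and 1 to 9 without 1 library. For 1 Mb bins, 0 higher and 0 lower became 242 and 1 with the block, and 0 to 16 higher without 1 library. The block changed no other call. At a coverage minimum of 30 the 1 higher and 3 lower regions stayed in the fit, and their p-values rose with the change in the other regions. Apart from this and the alternatives' own construction, the cause was not tested.

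The correlation between experiments (Pearson 0.00423, Spearman 0.0120) was 0.0141 and 0.0221 at a coverage minimum of 30 and 0.0117 (Pearson) on the log2 ratio scale, and was -0.0472 and -0.0337 with crosswise pairs, which a difference between experiments lowers. Of the regions past the adjusted threshold in edgeR, 0 in each direction also had p under 0.05 in the authors' table. At a coverage minimum of 1 this was 1 in each direction. Tests of the fixed gene lists, with their estimated correlation, fry, promoter regions, block and left-out libraries, were not run, since the tables named 2 of the lists' 377 genes. What depth limits at single regions was not tested apart from the choice of test: on the same simulated counts the edgeR fit recovered 3% and the quasi-binomial model 40% of 4-fold changes in odds.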

Other observations

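All tests in this part were chosen after the results, or values close to them, were seen. Bins of 1 Mb were ranked by the smaller of their differences in the 2 experiments, an order that differs from that by the mean difference. By this rule the leading gains were those at 13000001 to 14000000 on chromosome 20 (3.97 and 3.88 points in experiments 1 and 2), 53000001 to 54000000 on chromosome 7 (4.10 and 3.87 points) and 143000001 to 144000000 on chromosome 3 (3.64 and 4.95 points). The leading losses by the same rule were 2 on the X chromosome, at 17000001 to 18000000 (-2.17 and -7.26 points) and 101000001 to 102000000 (-2.77 and -2.02 points), and 1 on chromosome 1 at 79000001 to 80000000 (-1.89 and -3.77 points). These bins were chosen by their values, and none passed the adjusted threshold in limma (adjusted p between 0.168 and 0.456). With experiment as a block, 4 of the 6 passed in limma: those on chromosomes 20 (adjusted p = 0.0363), 7 (0.0453) and 3 (0.0124) and the first of those on the X chromosome (0.0121). The ranking picked bins with large changes in both experiments, so their passing is no separate support. The first of those on the X chromosome passed with unlike changes (-2.17 and -7.26 points), so passing did not need like changes in that fit. Of all 2311 bins, 242 passed as higher and 1 as lower in it.

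A hypothesis that X-linked regions gain less than autosomal regions was tested at matched methylation level. The gain of X-linked regions minus that of autosomal regions was -0.274 points in experiment 1 and -0.356 points in experiment 2, a mean of -0.315 points that exceeded the difference between experiments, which is consistent with the hypothesis. The unmatched means per chromosome had been seen before and the X chromosome was the lowest of 23, so the test restates what prompted it. Its unmatched mean difference of 0.939 points lay near those of chromosomes 21 (1.02 points) and 19 (1.04 points). The cause was not tested.

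A hypothesis that regions with a gene ID gain less than regions without one found no support at matched level: the differences were 0.0203 and 0.0850 points, a mean of 0.0527 points in the other direction. A hypothesis that bins differ in their gain in a way shared by both experiments found none either, since the correlation across 1 Mb bins was 0.0524, under the bound of 0.1 set for it.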
